A study of Mus musculus with 6 samples.

How the data were processed

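Adrenal glands of female mice aged 30 weeks, on a mixed 129 sv X CD1 background, were profiled by RNA sequencing in 3 wild-type (WT) and 3 Armc5 knockout (KO, Armc5(-/-)) samples. Per the labels' protocols, libraries that keep strand were made from 250 ng of RNA after removal of rRNA, and read from both ends at 100 bases on a NovaSeq instrument. Per the submitters' processing notes, Trimmomatic, STAR, Picard, StringTie and edgeR were used with the GRCm38 genome; the versions, the program that counted reads and whether it used strand are not given in the sources used here. The labels give the samples numbers 1 to 3 in each group and do not say whether each came from a separate animal, so the p-values measure the spread between these samples.

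The deposited table held whole-number read counts for 59699 loci in each of the 6 libraries, per the file headers raw and not normalized. The authors also deposited log2 CPM values, which differed from the log2 CPM of the library total by at most 0.0003 at the median of highly counted loci, and log2 values scaled to the count of Rn7sk (7SK RNA), which differed by at most 0.0004 from that ratio. The deposited log2 values entered only 1 alternative test, and the 4 columns of the authors' values per group were not used. Locus and gene lengths in base pairs, also deposited by the authors per the file headers, entered no test. Of the named loci, 1707 merged several genes, 621 of them several protein-coding genes, and 20 symbols had been turned into dates. Merged loci are written with a slash between the genes. Names of clones, predicted genes, pseudogenes, microRNAs and small nucleolar RNAs were left out where another name remained. A single symbol can therefore stand for a merged locus. Coordinates are those of the deposited table; 94.9% of 51180 single-gene loci had exactly the start and end of GENCODE M21, an annotation of GRCm38, which supplied the gene types. The 6596 loci without a gene name took 1.39% to 2.04% of the counts of a library and were left out of library sizes and of the main tests.

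Total counts per library ranged from 70547288 to 130573434. Counts of named loci were filtered with filterByExpr by group, scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, two-sided, R 4.3.3). P-values were adjusted over the 21358 tested loci by the Benjamini-Hochberg method, and a gene was called when its adjusted p was under 0.05. CPM values in the text use TMM-scaled library sizes, and the standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. A count of 0 over the 3 WT libraries was set to a floor of 3 counts over the group for a ratio; such ratios and 95% counting intervals (exact Clopper-Pearson) cover counting error only.

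The design, the alternatives, 35 gene lists and the rule for named genes were fixed before the data were examined. For the text, 4 members were taken from lists that passed or held a called gene and 1 from each other list, a convention set after the data were seen. The rule named Armc5, Rn7sk and Polr2a; the 12 genes with the largest rise and the 12 with the largest fall among annotated called genes with a mean of at least 1 CPM and no overlap between the groups; and up to 4 members of each list with the smallest p. A locus entered a list when all its protein-coding genes belonged to it. Lists with at least 3 measured members were tested with camera (limma 3.58.1, voom, preset inter-gene correlation of 0.01, two-sided, adjusted over 33 lists), which compares a list with all other genes. Beside it stand camera with an estimated correlation and fry, and member calls adjusted over the list alone. The lists covered steroidogenesis, cholesterol synthesis and uptake, fatty acid synthesis, markers of zona glomerulosa, zona fasciculata, X-zone, capsule and stroma, chromaffin, Schwann and glial, endothelial, macrophage, lymphocyte, adipocyte, erythroid, kidney and skeletal muscle cells, antigen presentation, subunits of RNA polymerases, elongation factors, cullin 3 ligase and proteasome, cell cycle, p53 targets, unfolded protein response, NRF2 targets, immediate early genes, cAMP signalling, Wnt targets, hormone receptors and genes known from human adrenal disease, interferon response, mitochondrially encoded genes, histones, ribosomal proteins and Y-linked genes.

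The alternatives were RLE size factors, total counts alone, equal Rn7sk counts, no filter beyond 1 count, at least 10 CPM in 3 libraries, the replicate number as a block, leaving out each library, DESeq2 1.42.0, limma-trend on the deposited log2 CPM, limma-voom with sample quality weights, glmTreat against a fold of 1.2, a log2 fold change of at least 1, and leaving out abundant RNAs before scaling. Leaving out WT replicate 1 with KO replicate 3, or loci of hepatocyte genes, was chosen after seeing the data. The gene test was tested on simulated data drawn from the real means, dispersions and library sizes, with 20756 loci tested. It called 34% of 100 genes changed 2-fold and 82% of 100 genes changed 4-fold, with 16 of the calls false (12.1%).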

Results

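RNA from 3 WT and 3 Armc5 KO adrenal gland samples of female mice was compared to ask which transcripts differ when Armc5 is lost. ARMC5 is an adaptor of a cullin 3 ubiquitin ligase that acts on the large subunit of RNA polymerase II, and its gene is mutated in human bilateral macronodular adrenal hyperplasia. The WT libraries held 119082215, 130573434 and 89806230 counts, and the KO libraries 104737109, 70547288 and 122924298. Mitochondrial loci took 16.8%, 14.8% and 17.6% of the counts of named loci in WT and 13.3%, 13.2% and 13.7% in KO. KO replicate 3 held 295610 counts of Alb, the liver's serum albumin, against 1289 in WT replicate 1 and at most 167 in the other libraries. Each of the 6 measured genes of a hepatocyte list written after the data were seen was at least 10-fold higher in that library than in every other one, and they took 0.302% of its counts. None of the Y-linked genes passed the count filter in these female samples.

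Armc5 was lower in every KO library, with 395, 269 and 473 counts in KO against 2763, 3263 and 2233 in WT. The gene (GRCm38 chromosome 7, 128237342 to 128245100) stood at 26.8 ± 1.35 CPM in WT and 3.59 ± 0.0633 CPM in KO (SD, n = 3 each), a log2 fold change of -2.90 (SE 0.10), which is 7.47-fold lower (edgeR quasi-likelihood test, adjusted p = 0.00041). Which part of the gene was deleted is not stated in the labels. The locus 9130023H24Rik (chromosome 7, 128234458 to 128238031), which overlaps the start of Armc5 and was looked at after its values were seen, fell 5.56-fold from 13.5 ± 1.03 to 2.42 ± 0.319 CPM (edgeR adjusted p = 0.00465), and reads of the overlapping genes may not be told apart. Rn7sk, the 7SK RNA that RNA polymerase III makes and that the authors used as a reference, did not pass the test, with a log2 fold change of -0.20 (SE 0.15, edgeR adjusted p = 0.462) that turned to 0.04 with total counts alone. Polr2a, which encodes the large subunit of RNA polymerase II, was at 291 ± 59.3 CPM in WT and 227 ± 19.4 in KO and did not pass either (log2 fold change -0.36, SE 0.17, edgeR adjusted p = 0.268).

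**Figure D1:**
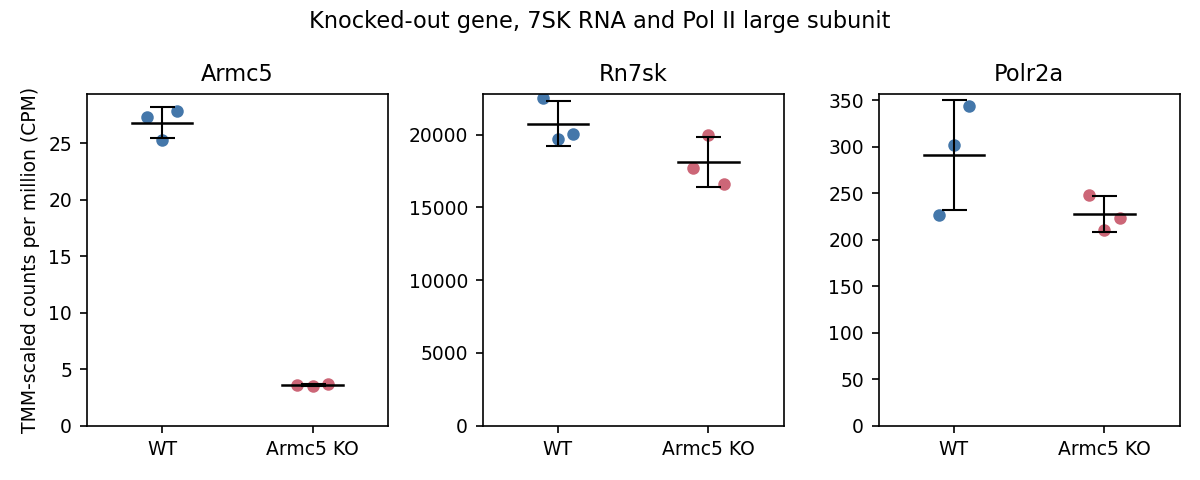
Expression of Armc5, Rn7sk and Polr2a in TMM-scaled CPM (vertical axes, from 0) in WT and Armc5 KO adrenal glands; points are libraries, horizontal lines means and error bars SD (n = 3). The 3 KO libraries lie below the 3 WT libraries for Armc5.

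Several of the genes that rose most in KO adrenal glands were barely counted in WT. Dnah9, an axonemal dynein heavy chain, rose 71.9-fold from 0.11 ± 0.0362 to 8.17 ± 1.07 CPM (SD, n = 3 each), and Foxj1, the transcription factor of motile cilia, rose 17.7-fold to 2.62 ± 0.26 CPM. Nptx2, a secreted protein of synapses, rose 117-fold to 4.42 ± 0.349 CPM. Ren1, which encodes renin, rose 27.2-fold from 3.71 ± 2.47 to 101 ± 58.1 CPM, although Ren2, a near-identical gene of some mouse strains, may share its reads. Genes that fell included the chemokine Ccl28, 78.3-fold lower, and Arpc5, a subunit of the Arp2/3 complex that nucleates actin filaments, which fell 2.66-fold from 106 ± 6.7 to 40.0 ± 3.29 CPM.

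Of 21358 loci tested, 393 were called, 301 higher and 92 lower in KO, so that 76.6% of the calls were higher (edgeR quasi-likelihood test, adjusted p under 0.05). All 393 had no overlap between the groups, which 30.5% of the tested loci showed and chance gives for 10%. A change of at least 2-fold was seen in 240 of the called loci. The split of the calls depended on scaling: with total counts alone 639 of 674 calls (94.8%) were higher, and with equal Rn7sk counts 669 of 711 (94.1%). In these fits the median log2 fold change of all genes was 0.22 and 0.19, against -0.0063 with TMM scaling. Without WT replicate 1 there were 383 calls, 180 of them lower. The number of calls was 644 without WT replicate 2, 20 without WT replicate 3, 15 without KO replicate 1, 22 without KO replicate 2 and 37 without KO replicate 3. Of the 393 calls, 192, 296, 19, 13, 17 and 30 were called again in these fits, in the same order. Of 31 called genes taken by the rule for named genes, Armc5, Dnah9 and Rad51ap2 were called in all 6 fits, and Ren1 (edgeR adjusted p from 0.0595 to 0.139) and Psmd8 (0.0523 to 0.148) in none.

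The other genes with the largest rises under the rule for named genes were of several kinds. Actn2, the alpha-actinin of muscle, had no counts in WT and 2.09 ± 0.728 CPM in KO, a ratio of 224 against a floor of 3 counts over the group, with a lower 95% counting limit of 181. Pcdh8, a protocadherin, had 3 counts in WT and 2017 in KO, a ratio of 661 with a 95% counting interval of 226 to 3207, and Dnah3, another axonemal dynein, had 5 and 1707, a ratio of 336 with an interval of 144 to 1035. Rnu1b1 and Rnu1b2, copies of the U1 small nuclear RNA, rose 55.9-fold and 60.2-fold, but they had equal means in WT and are near-identical, so that their reads cannot be assigned to one copy. Dio3, the deiodinase that inactivates thyroid hormone, rose 19.8-fold, the water channel gene Aqp3 33.7-fold and Rad51ap2 15.9-fold. The edgeR adjusted p of these genes lay between 0.00465 and 0.0274.

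The other genes with the largest falls under the rule for named genes fell between 2.62-fold and 23.3-fold. Loci with clone names, such as 9130023H24Rik, did not count as annotated and were not ranked. Mmp27, a matrix metalloproteinase, fell 23.3-fold, Folh1, a folate hydrolase, 11.7-fold and Mme, the membrane endopeptidase neprilysin, 4.83-fold from 23.1 ± 9.48 to 4.78 ± 1.35 CPM. Gdf15, a stress-induced growth factor, fell 4.92-fold and F3, tissue factor of blood clotting, 3.42-fold. Falls were also measured for Ifit1bl1 (4.12-fold), the sodium channel subunit Scn4b (3.01-fold), the merged locus Rassf4/Zfp422 (2.89-fold) and Adhfe1 (2.62-fold). The largest edgeR adjusted p in this group was 0.0494, for Scn4b, and with equal Rn7sk counts Scn4b and Adhfe1 were no longer called (adjusted p = 0.0763 and 0.0550).

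Markers of chromaffin cells, the catecholamine-producing cells of the adrenal medulla, rose as a list in KO glands, with a median log2 fold change of 0.79 over 18 measured members (camera adjusted p = 7.04e-09, adjusted p = 0.713 with an estimated correlation). The members called were Chga, chromogranin A of secretory granules, which went from 617 ± 97.3 to 1129 ± 27.3 CPM (SD, n = 3 each), Dbh, the enzyme that makes noradrenaline, from 344 ± 49.0 to 595 ± 16.7, and the transcription factors Hand2, from 39.7 ± 8.23 to 75.7 ± 1.23, and Phox2a, from 28.3 ± 4.12 to 48.8 ± 4.58. These 4 members were higher, none was lower and 14 were not called over all genes, while 15 were higher when adjusted over the list alone and 14 by DESeq2. In 14 of the 18 members every KO library lay above every WT library. Ret and Penk had negative log2 fold changes of -0.38 and -0.08. When 1 library was left out, these 4 genes were called without WT replicate 2 (edgeR adjusted p from 0.0209 to 0.0398) but not without WT replicate 1 (0.0551 to 0.0777), WT replicate 3 (0.132 to 0.164), KO replicate 1 (0.168 to 0.185), KO replicate 2 (0.154 to 0.158) or KO replicate 3 (0.122 to 0.128).

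**Figure D2:**
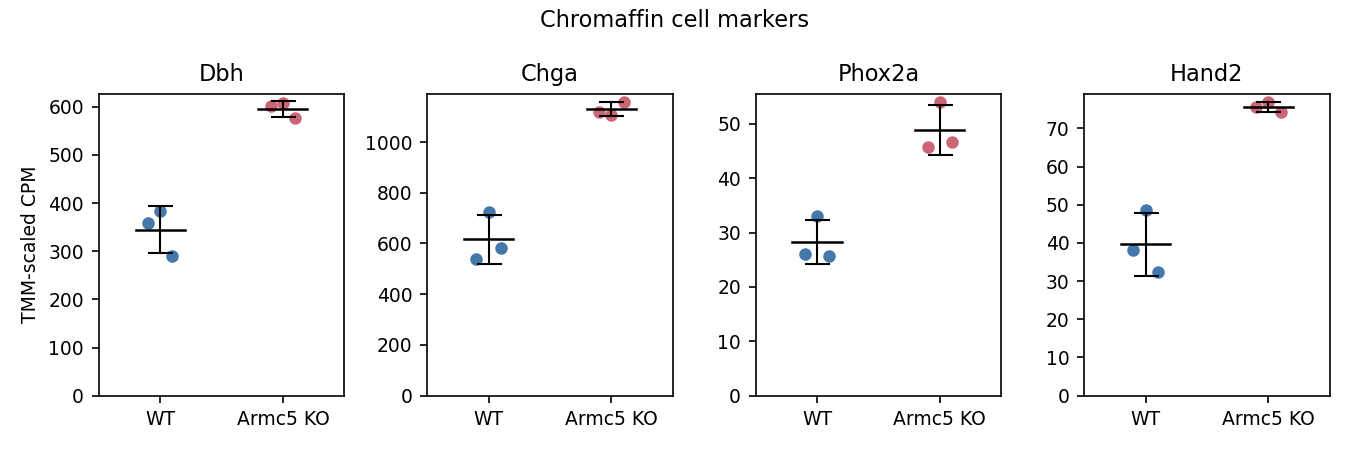
Expression of 4 chromaffin cell markers in TMM-scaled CPM (vertical axes, from 0); points are libraries, horizontal lines means and error bars SD (n = 3). Every KO library lies above every WT library for Dbh, Chga, Phox2a and Hand2.

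Genes of the interferon response rose as a list, with a median log2 fold change of 1.81 and all 10 measured members positive (camera adjusted p = 2.39e-07, adjusted p = 0.713 with an estimated correlation). Zbp1, a sensor of nucleic acids, was at 3.07 ± 1.7 CPM in WT and 12.9 ± 1.13 in KO (SD, n = 3 each), Ifi44 at 29.7 ± 14.6 and 104 ± 5.44, Bst2, the antiviral protein tetherin, at 21.6 ± 7.58 and 47.3 ± 4.94, and Ifit3 at 12.5 ± 9.55 and 59.0 ± 12.9. None of the 10 was called by edgeR over all genes, 10 had an unadjusted p under 0.05, 9 were higher by DESeq2, and 10 were higher when adjusted over the list alone. Of the antigen presentation list, Tap1, a peptide transporter, rose 1.99-fold from 13.6 ± 1.5 to 27.1 ± 4.06 CPM (edgeR adjusted p = 0.0385), the other 6 members were not called, H2-K1/H2-K2, B2m and Cd74 among them with log2 fold changes of 0.58, 0.45 and 0.14, and the list did not pass (adjusted p = 0.0981). It passed, as higher, in 3 of 14 alternatives, which were without WT replicate 2 (adjusted p = 0.0109), without KO replicate 2 (0.0182) and with at least 10 CPM required (0.0459).

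**Figure D3:**
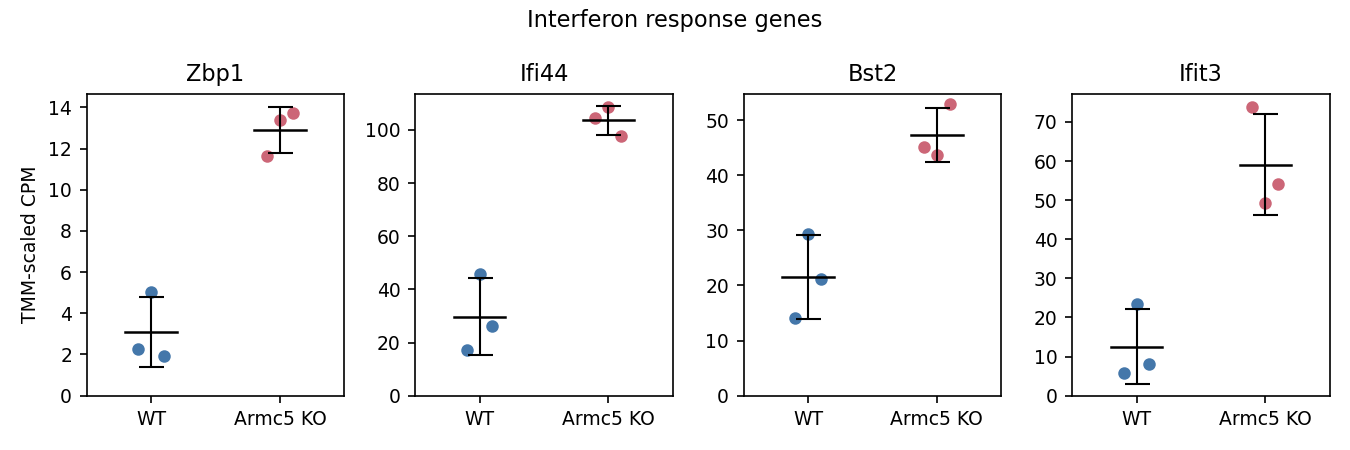
Expression of the 4 interferon response genes with the smallest p, in TMM-scaled CPM (vertical axes, from 0); points are libraries, horizontal lines means and error bars SD (n = 3). Every KO library lies above every WT library in the 4 panels.

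Genes of steroid hormone synthesis, the main work of the adrenal cortex, were lower as a list, with 10 of 12 members negative, a median log2 fold change of -0.28 and no member called by edgeR (camera adjusted p = 0.0391, adjusted p = 0.713 with an estimated correlation). Its median was -0.04 with total counts alone and -0.07 with equal Rn7sk counts, which relative to the median of all genes is -0.26 and -0.27. An unadjusted p under 0.05 was found for 3 members, and DESeq2 called 2 lower. With the preset correlation, splits of the libraries that mixed the genotypes passed up to 17 lists, against 9 for the real split. Star, which brings cholesterol into mitochondria, had a log2 fold change of -1.10 (SE 0.29), Cyp11a1, the enzyme of the first step, -0.58 (SE 0.17), the merged locus Cyp11b1/Cyp11b2 -0.63 (SE 0.24) and Mrap -0.48 (SE 0.24), with edgeR adjusted p from 0.103 to 0.289. The list did not pass camera without WT replicate 1 (adjusted p = 0.296), without KO replicate 2 (0.0709), without WT replicate 1 and KO replicate 3 (0.234) or with at least 10 CPM required (0.222). Endothelial markers were lower as a list (camera adjusted p = 0.000714, adjusted p = 0.713 with an estimated correlation), all 9 members being negative. None was called by edgeR over all genes, 5 had an unadjusted p under 0.05, DESeq2 called 3 lower and 5 were lower when adjusted over the list alone. The median of -0.39 was -0.17 with total counts alone and -0.19 with equal Rn7sk counts, which relative to the median of all genes is -0.39 and -0.38. Examples are Cdh5 (-0.39), Pecam1 (-0.36), Flt1 (-0.50) and Tek (-0.51) on the log2 scale. The 3 erythroid loci, Hba-a1/Hba-a2, Hbb-bt/Hbb-bh3/Hbb-bs and Alas2, had log2 fold changes of -1.33, -1.12 and -1.05 (camera adjusted p = 0.0385, 0.713 with an estimated correlation, and 0.0996 by camera without WT replicate 1).

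Subunits of RNA polymerase II were lower as a list relative to other genes, all 13 members having negative log2 fold changes with a median of -0.20 and none called (camera adjusted p = 0.0111, adjusted p = 0.713 with an estimated correlation). Polr2m had a log2 fold change of -0.47 (SE 0.08), Polr2b -0.27 and Polr2i -0.25, against -0.36 for Polr2a. In the cullin 3 ligase and proteasome list 31 of 33 members were negative and Psmd8, a proteasome subunit, was the 1 called, 1.57-fold lower (edgeR adjusted p = 0.0385, and 0.188 with equal Rn7sk counts), while Psmd2 (-0.37), Psmd13 (-0.29) and Keap1 (0.46) were not called. Of 79 ribosomal protein loci 70 were negative and none was called, Rps2 (-0.46), Rpl35 (-0.33), Rpl29 (-0.28) and Rpl32 (-0.25) having the smallest p. The 5 mitochondrially encoded loci had a median of -0.50, with mt-Nd3 at -0.69, mt-Nd4/mt-Nd4l at -0.76 and mt-Co2 at -0.44, and none was called. That median was -0.26 with total counts alone and -0.29 with equal Rn7sk counts, which relative to the median of all genes is -0.48 for both. An unadjusted p under 0.05 was found for 1 polymerase II, 26 ribosomal and 3 mitochondrial loci, and DESeq2 called 1, 1 and 3 lower. The cullin 3, ribosomal and mitochondrial lists passed camera with adjusted p of 2.46e-05, 2.42e-08 and 0.0056, and none did with an estimated correlation (adjusted p = 0.713 for each). With total counts alone the medians of the polymerase II, cullin 3 and ribosomal lists turned to 0.03, 0.02 and 0.04, and the ribosomal list did not pass (adjusted p = 0.0893). With equal Rn7sk counts the medians of the polymerase II and ribosomal lists turned to 0.01 and 0.02, which relative to the shift of all genes is -0.18 and -0.17. The polymerase II list then did not pass (adjusted p = 0.0573, with 0.0835 for total counts alone and 0.14 with at least 10 CPM required). The mitochondrial list did not pass without WT replicate 1 and KO replicate 3 (0.0622).

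**Figure D4:**
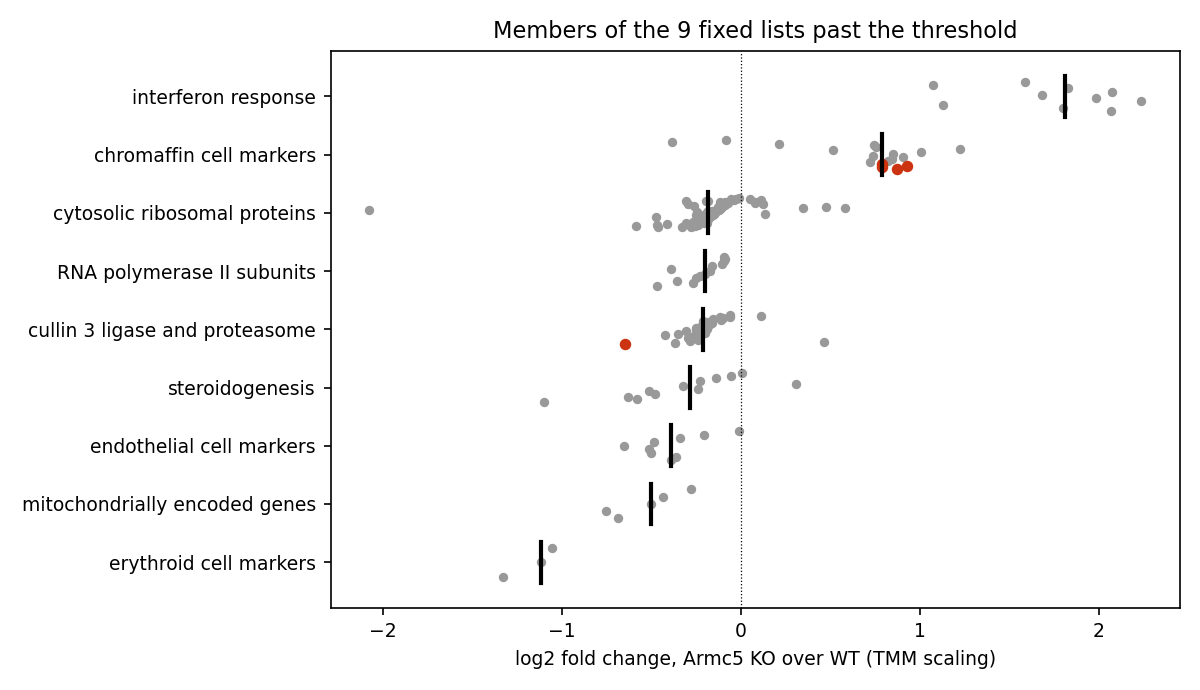
Log2 fold change (KO over WT, horizontal axis) of each measured member of the 9 lists that passed the camera test, 1 row per list; red points are called genes, grey points are not called and black bars are medians. The interferon and chromaffin medians lie at 1.81 and 0.79, and the medians of the other 7 lists lie below 0 with TMM scaling, while those of the polymerase II, cullin 3 and ribosomal lists lie above 0 with total counts alone.

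The other cell marker lists did not pass the camera test. Macrophage (adjusted p = 0.0734), lymphocyte (0.0734), Schwann and glial (0.0963), adipocyte (0.283), capsule and stroma (0.30) and skeletal muscle (0.304) markers had no member called by edgeR, and Lrp2 was the 1 kidney marker measured, with a log2 fold change of -0.32. The members with the smallest p were Fcgr1 (0.92), Igkc with merged variable segments (-1.80), Fabp7 (-1.27), Ucp1 (-4.68), Dcn (-0.73) and Mylpf (1.93), and none of these passed the edgeR test. An unadjusted p under 0.05 was found for 6 macrophage, 3 lymphocyte and 5 Schwann and glial markers, of which DESeq2 called 4, 2 and 1. Several of these lists passed, as lower relative to other genes, under some of the alternatives. The macrophage list passed in 6 of 14 (adjusted p from 0.000108, without WT replicate 1, to 0.422), the lymphocyte list in 7 of 13 (0.00184 to 0.453), among them without WT replicate 1 (0.0469), WT replicate 3 (0.00547) or KO replicate 3 (0.01001), and the Schwann and glial list in 6 of 13 (0.0116 to 0.425), among them without WT replicate 1 (0.0496) or WT replicate 3 (0.0404). The adipocyte list passed in 3 of 14 (0.0404, without WT replicate 3, to 0.839) and the capsule and stroma list in 1 of 14 (0.0155, without WT replicate 1 and KO replicate 3). Of the cortical zones, the zona glomerulosa list (0.217), with Dab2 at 0.42, the zona fasciculata list (0.234) and the X-zone list (0.95) did not pass, although the zona fasciculata list did, as lower, without WT replicate 2 (0.0171). The X-zone median was -0.41 (-0.20 with total counts alone), with Thrb at -0.41, although camera placed that list higher. Cholesterol (0.956) and fatty acid synthesis (0.084) did not pass, with Pmvk at 0.63 and Fads1 at -0.83. Fatty acid synthesis passed, as lower relative to other genes, in 6 of 14 alternatives (adjusted p from 0.000119 to 0.419), among them total counts alone (0.0204), equal Rn7sk counts (0.0246), without WT replicate 2 (0.0263) and without KO replicate 3 (0.000119). The cholesterol and p53 lists had medians of -0.02 and -0.08 (0.21 and 0.15 with total counts alone) but means of 0.03 and 0.07.

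Signalling and stress lists did not pass camera. Adjusted p was 0.57 for cAMP and protein kinase A signalling (Prkar1b 0.43), 0.218 for Wnt targets (Lgr5 0.71), 0.57 for the hormone receptors of human macronodular hyperplasia (Avpr1a 0.77) and 0.184 for genes mutated in human adrenocortical disease (Ctnnb1 -0.45). It was 0.105 for the cell cycle (Ccne1 0.91), 0.925 for p53 targets (Mdm2 -0.39), 0.246 for the unfolded protein and integrated stress response (Ddit3 0.59) and 0.956 for NRF2 targets (Gclc 0.61). RNA polymerase I and III subunits (Crcp 0.92) gave 0.217, elongation factors (Supt5 -0.33) 0.184 and immediate early genes (Dusp1 -0.65) 0.0897. Among 43 histone loci, which gave 0.184, Hist2h2aa2/Hist2h2ac was called, 1.6-fold lower (edgeR adjusted p = 0.0389, and 0.151 with equal Rn7sk counts), and Hist1h4h (-0.78), Hist2h4 (-0.68) and Hist1h1d/Hist1h1c/Hist1h2bb (-0.83) were not. Under the alternatives 4 of these lists passed, as lower relative to other genes. The cell cycle list passed in 6 of 14 (adjusted p from 1.59e-06, without WT replicate 1, to 0.837), among them without KO replicate 2 (0.0253), total counts alone (0.0164) and equal Rn7sk counts (0.0246). The immediate early list passed in 6 of 14 (0.00493, with total counts alone, to 0.546), among them without WT replicate 2 (0.0263), WT replicate 3 (0.00832) or KO replicate 3 (0.0206). The histone list passed without WT replicate 1 (0.0496) and without KO replicate 2 (0.01003), and the genes mutated in human adrenocortical disease without WT replicate 2 (0.0326).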

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

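The tests over other windows, over splits of the libraries, and of the chromaffin and interferon lists were chosen after the result was seen; the Fisher test around Armc5 was set before its result was seen. Outside the named genes, loci without a gene name, which no comparison of the report used, held a signal above the WT libraries: 85 of 5101 tested loci were called and all 85 were higher in KO (edgeR quasi-likelihood test with the library sizes of the named loci), with none lower, and 997 had an unadjusted p under 0.05. The share called, 1.67%, was near the 1.84% of named loci, and loci without a gene name were shifted upward in general, with a median log2 fold change of 0.28 and 1.77% to 2.04% of the counts of a KO library against 1.39% to 1.56% in WT. A locus on chromosome 3 (108547303 to 108552481) went from 0.142 ± 0.0464 to 9.21 ± 0.16 CPM (SD, n = 3 each), a log2 fold change of 6.01 (SE 0.30, adjusted p = 0.000864). For 9 of the 85 the nearest tested protein-coding gene was itself called, beside 1.84% of all named loci. The 85 loci had 70 different nearest genes, and some lay side by side on the same strand. They may be pieces of fewer transcripts and are not all separate results.

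Chromaffin markers rose while endothelial markers were lower as a list. The upper quartile of the endothelial log2 fold changes was -0.34, below the lower quartile of the chromaffin list. A lower share of cortical cells would raise both lists only if the vessels of the cortex were not lost with it. The steroidogenesis list was lower too, so this comparison cannot decide whether the share of cortical cells was lower. A larger share of chromaffin cells, with unchanged expression per cell, needs 1 shared fold only if all markers come evenly from chromaffin cells alone. Whether they do was not tested. The 18 members ranged from -0.38 for Ret to 1.23 for Npy, with 2 negative. An exact permutation test of the differences between the 18 gave p = 0.1, the smallest that 10 splits of the libraries allow. Such a share therefore cannot be told apart from a change of expression. A chi-squared test from the SEs (p = 0.00152) and an analysis of variance with the library as a block (p = 0.000139) speak against a shared fold of all 18. Both are approximate and treat markers of the same libraries as independent. The lowest members were Ret, Penk (-0.08) and Ddc (0.22). The exact test was the last of 4 versions. The earlier 3 used 10 members picked after their values were seen, which ranged from 0.75 to 1.01, and found no difference (exact p = 0.9). Cell numbers were not measured here.

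Interferon response genes rose while the medians of the macrophage and lymphocyte lists were -0.44 and -0.59 (-0.23 and -0.39 with total counts alone). The higher of the upper quartiles of the macrophage and lymphocyte lists was a log2 fold change of -0.0649. This lies below the lower quartile of the interferon list (1.61), so lymphocyte markers did not rise as the interferon genes did. That bar is high, so the comparison cannot exclude a smaller rise in lymphocytes. Of the 12 lymphocyte markers 9 were negative and 3 positive, and the list did not pass (camera adjusted p = 0.0734). For macrophages the comparison cannot decide either, because the WT libraries differed from each other. Cd68 was at 16.1 to 169 CPM in WT and at 14.6 to 21.0 CPM in KO. Of the macrophage markers 10 were negative and 2 positive, among the latter Fcgr1 with a log2 fold change of 0.92. A single KO library does not account for the rise of the interferon list. In 9 of its 10 members every KO library lay above every WT library. The genotype, and an infection or another exposure shared by the KO samples, stay open and were not tested.

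Called loci were more frequent near Armc5. Within 20 Mb on chromosome 7, with Armc5 left out, 16 of 477 loci (3.35%) were called, against 376 of 20880 (1.80%) elsewhere (one-sided Fisher's exact test, p = 0.0156, and 0.0300 without 9130023H24Rik). Of 373 other windows of 40 Mb, which overlap each other, 4.02% held as high a share, on 6 other chromosomes, and over 8 tilings of windows that do not overlap the share was 0% to 7.69%, so that clustering along every chromosome stays open. DNA of another parental strain around the targeted gene is a candidate explanation for part of these calls, and a local effect of the deletion itself was not tested. Dnah3 and Igf2 were among the calls (log2 fold changes of 8.24 and 1.03) but rose along with genes on other chromosomes. Dnah9 (6.17, chromosome 11) and Ccno (3.54, chromosome 13) are also cilium genes, and Dlk1 (1.00, chromosome 12) and Nap1l5 (1.02, chromosome 6) are also imprinted. In the cilium and imprinted lists, written after the values were seen, 4 of 48 and 5 of 27 members were negative.

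Of the 10 splits of the 6 libraries into equal groups, 1, the real one, gave as many called genes (393, against at most 2 in another split), and 6 gave as many lists past the threshold (9, against up to 17). These splits are too few for a share under 0.05. For the lists, some splits that mixed the genotypes gave as many or more, so the count of 9 does not set the genotypes apart. Passing camera with the preset correlation is therefore weak evidence for a list.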

How the results depend on the processing

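The fits without WT replicate 1 and KO replicate 3 together, and without hepatocyte loci, were chosen after the data were seen; the other alternatives were planned. Of the 393 calls, 5 to 296 were called again with the replicate block or with 1 or 2 libraries left out, 332 and 335 with equal Rn7sk counts and total counts alone, 348 by limma-trend and 227 with at least 10 CPM (where 238 were tested). None changed sign in the 20 alternatives, which says little, because all 393 had no overlap between the groups and 2 alternatives use the same fit. Calls were 380 with RLE factors, 336 without a low-count filter, 303 with at least 10 CPM, and 393 without abundant RNAs or without hepatocyte loci. Total counts alone gave 674 calls (639 higher, 35 lower) and 14 lists past the threshold, and equal Rn7sk counts 711 (669 higher, 42 lower) and 15 lists. The median log2 fold change of all genes was 0.22 and 0.19 with these scalings. TMM scaling by construction holds the typical gene near 0 (median -0.0063), so it could not show a shift of all genes. Total counts fix the sum of each library and could not show it either. Equal Rn7sk counts could show it only if Rn7sk itself did not change, which was not tested. No low-count filter gave 15 lists. Leaving out 1 library gave 15 to 644 calls (12 to 528 higher, 3 to 180 lower) and 9 to 14 lists, and leaving out WT replicate 1 with KO replicate 3 gave 16 calls (13 higher, 3 lower), with fewer samples. DESeq2 gave 2157 (1401 higher, 756 lower), limma-trend on the deposited log2 CPM 1015 (956 higher, 59 lower), and limma-voom with sample quality weights 2631 (1647 higher, 984 lower). The stricter glmTreat gave 172 (142 higher, 30 lower) and a log2 fold change of at least 1 gave 240 (203 higher, 37 lower). Camera with an estimated correlation gave 0 lists, and fry 1, the ribosomal proteins (adjusted p = 0.0483). With the replicate number as a block, 5 genes were called (4 higher, 1 lower); same-numbered samples did not deviate together across genes (correlations of -0.09, 0.01 and -0.14), and not every sample correlated best with its own number, so the numbers are not read as pairs. Where a cause is not named, the cause was not tested.

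Results that had not passed the test turned their sign as follows, and none passed it then. The log2 fold change of Rn7sk was 0.0377 with total counts alone and 0.0260 by limma-trend, that of Cd74 -0.0435 without KO replicate 3 (up to 0.43 without another library) and -0.17 without WT replicate 1 and KO replicate 3, that of Lrp2 0.10 with quality weights and that of Akr1c18 -1.24 without KO replicate 1 (up to 8.92 without another library). For Pik3c2g it was 1.40 with the replicate block, 5.22 without WT replicate 1 (down to -2.46 without another library), 5.48 without both libraries, 1.64 by limma-trend and 3.48 with quality weights. For lists the values are adjusted p. Total counts alone turned cholesterol synthesis and uptake (1.00), X-zone (0.807), RNA polymerase I and III (0.859), Pol II pausing and elongation factors (0.6915) and p53 targets (1.00), and equal Rn7sk counts X-zone (0.849). No filter turned cholesterol (0.976) and NRF2 targets (0.677), at least 10 CPM cholesterol (0.67), p53 (0.67) and NRF2 (0.593), and the block X-zone (0.838). Leaving out both libraries turned cholesterol (0.675), p53 (0.675) and hormone receptors (0.956), and fry cholesterol (0.950) and NRF2 (0.887). Leaving out 1 library turned cholesterol, X-zone, p53 and NRF2 in some of the 6 fits, and over all 6 fits adjusted p was 0.119 to 0.877, 0.515 to 0.938, 0.576 to 0.982 and 0.257 to 0.838 in that order. At these depths and 3 libraries a group, simulated 2-fold changes of loci with a mean of at least 1 CPM were called in 34% of cases.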

Other observations

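The lists, tests and genes in this part were chosen after the values were seen, and list p-values were adjusted over 6 lists. The list p-values therefore reflect that choice, are no test of it, and cannot be compared with those of the fixed lists. Genes of motile cilia had a median log2 fold change of 0.92 over 48 measured (camera adjusted p = 3.44e-12, 0.0344 with an estimated correlation). Of these, 44 were positive and 4 negative, and 8 were called, all higher in KO. Some better counted members changed little and were not called. Dnah7b, Ccdc114 and Cfap69, at 17.1, 13.8 and 10.2 CPM in WT, had log2 fold changes of 0.06, 0.32 and 0.25. Besides Dnah9 and Dnah3, Ccno, a regulator of cilium formation, rose 11.6-fold from 0.443 ± 0.0686 to 5.19 ± 1.05 CPM (SD, n = 3 each), Erich3 3.41-fold and Cfap46 2.43-fold. Imprinted genes were higher too, with 5 of 27 called and a median of 0.54 (camera adjusted p = 6.03e-07, 0.0141 with an estimated correlation). The Igf2 locus spans chromosome 7, 142399464 to 142669942, and may hold reads of other genes. Dlk1 rose 2.0-fold from 259 ± 37.9 to 517 ± 20.4 CPM, Igf2, a fetal growth factor, 2.04-fold, Nap1l5 2.03-fold and Plagl1 1.87-fold, log2 fold changes of 1.03, 1.02 and 0.90 for the last 3, beside a median of 0.79 for the chromaffin list. Single genes outside the fixed interferon list, picked because they rose and not tested as a group, were Herc6 (2.56-fold), Eif2ak2, the double-stranded RNA kinase PKR (1.98-fold), and Oasl1 (5.11-fold), while Ifit1bl1, of the Ifit gene family, fell 4.12-fold.

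Genes of the actin cytoskeleton were lower, with 6 of 23 called and a median log2 fold change of -0.49 (camera adjusted p = 1.69e-12, 0.0141 with an estimated correlation). Rhob, a small GTPase, fell 1.85-fold from 288 ± 13.0 to 156 ± 7.7 CPM, Tpm4 1.73-fold and Tagln 2.05-fold. The Tpm4 locus spans chromosome 8, 72130174 to 72539248, and the Tagln locus chromosome 9, 45346779 to 45936058. Both may hold reads of other genes. Tagln marks smooth muscle, as do Acta2 (-1.26 on the log2 scale) and Myl9 (-0.55), which were not called, and the endothelial list had a median of -0.39. Lysosome and V-ATPase genes had 4 of 31 called, all lower, with a median of -0.54 (adjusted p = 1.78e-13, 0.0835 with an estimated correlation). The proton pump subunits Atp6v1h and Atp6v1a fell 1.87-fold and 1.73-fold. Some other members of the list, not called, were highest in WT replicates 2 and 3, as was the macrophage marker Cd68. Psap was at 1005, 3110.5 and 2146 CPM in WT replicates 1 to 3 and at 882, 796 and 883 CPM in KO replicates 1 to 3, Ctsb at 1214, 2456 and 1963 CPM in WT replicates 1 to 3 and at 968, 882 and 915 CPM in KO replicates 1 to 3, and Cd68 at 16.1, 169 and 79.5 CPM in WT replicates 1 to 3 and at 14.6, 21.0 and 17.0 CPM in KO replicates 1 to 3. Of 10 immunoglobulin constant genes Ighg2b (-3.43) and Ighg2c (-6.19) fell on the log2 scale, the list giving a camera adjusted p of 0.00252 and 0.189 with an estimated correlation. Both genes were low in WT, at 1.37 ± 0.431 and 1.62 ± 0.254 CPM. Ighg2c had 189, 211 and 109 counts in WT replicates 1 to 3 and 0, 0 and 7 in KO replicates 1 to 3. Strain differences at these genes, in mice of mixed background, were not examined. The small RNAs Rny1 and Rny3 fell 2.53-fold and 2.33-fold.

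Some genes differed between libraries of 1 group. Akr1c18, an X-zone enzyme, was at 113, 0.0774 and 0.175 CPM in WT replicates 1 to 3 and at 142, 2.77 and 29.1 CPM in KO replicates 1 to 3. Pik3c2g, another X-zone gene, was at 39.7, 0.116 and 0.262 CPM in WT replicates 1 to 3 and at 15.9, 0.407 and 4.41 CPM in KO replicates 1 to 3. Gpnmb, a gene of lipid-laden macrophages, was at 1.02, 1418 and 599 CPM in WT replicates 1 to 3 and at 12.3, 1.79 and 9.0 CPM in KO replicates 1 to 3.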
